A study of Homo sapiens with 6 samples.

How the data were processed

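Gene expression was measured on Illumina HumanHT-12 bead arrays in 3 human primary effusion lymphoma cell lines, BCP1, BCBL1 and BC1. Each line was cultured with vehicle or with the ribonucleotide reductase inhibitor 3-AP at 2.5 µM for 48 h, which gave 6 arrays, 3 per group and 1 pair per line. Per the labels' protocols, total RNA was extracted with TriZol and labelled as cRNA with a kit for Illumina bead arrays. The scanner software, the background step and the normalization are not given in the sources used here.

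The authors' non-normalized table holds a linear signal intensity and a detection p-value per probe and array, per the file headers. The authors' processed table holds one linear intensity per probe and array for 47323 probes. The sorted processed values of the vehicle and 3-AP arrays of a line were nearly equal, so the deposited intensity values look quantile normalized within each line and not across lines. In the non-normalized table, both columns named for BCP1 equalled the processed BCBL1 columns in 100% of probes, and the deposited p-value columns named for BCP1 equalled those of BCBL1 in 99.985% of probes for vehicle and 99.989% for 3-AP. Signals before normalization and detection p-values were therefore used for 4 arrays, those of BCBL1 and BC1. The columns named for BCP1 in that table entered no test.

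The design fixed before the data were examined called for the non-normalized signals. Because these could be used for 4 arrays, the processed table was taken as the starting point for all 6. The background was estimated with the detection p-values (limma nec, offset 16), where each BCP1 array was given by rank the mean p-value profile of the other 4 arrays. The signals were then quantile normalized across the 6 arrays and log2 transformed. The fixed design said nothing of this substitution, and both the rank step and the double normalization can change a value.

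Of the 47323 probes, 13 with a signal of 0 on at least 1 array were left out. A probe was kept if detected on at least 3 arrays, at a detection p under 0.05 or, for BCP1, within the top 38.12% of signals, the mean share detected on the other arrays. This kept 17988 probes. The probe annotation gave 1 gene symbol for 30113 probes and several for 8, and 17202 probes were unnamed here. The kept probe with the highest mean log2 value stood for its gene, which left 14627 features, 10456 with a symbol and 4171 unnamed probes. Of 136 genes named for the 3-AP comparison and the lists, 31 had several kept probes, and for 2 of these, HINT3 and IL10, another probe moved the other way. The genes named as highest in a line were not in this probe check. A gene not above background on any array of a group was given only a bound ("at least N-fold"): the brighter group's mean over the dimmer group's mean of, per array, the higher of the probe's own signal and the lowest signal among detected probes. These bounds hold only after the background subtraction, and the fold in the deposited table is given beside each.

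Tests were run in R 4.3.3 with limma 3.58.1. Each feature was fitted with cell line as a block and agent as the effect, with lmFit and eBayes, and adjusted by Benjamini-Hochberg over all features at 0.05. The fit had 2 residual degrees of freedom and a prior of 3.20. The labels give 1 vehicle and 1 treated sample per line, which is where the pairing comes from. The deviations from the group means of the vehicle and the treated array of a line correlated across features at 0.71 for BCP1, 0.76 for BCBL1 and 0.86 for BC1. Crossed between BCP1 and BCBL1 the values were 0.58 and 0.59, and crossed with BC1 they were -0.73 to -0.78. The check therefore told BCP1 from BCBL1 far less clearly than it told either from BC1. Gene lists fixed before the data were examined, 26 with at least 5 measured members, were tested two-sided with camera at a preset inter-gene correlation of 0.01. Differences between lines were tested with the moderated F test of both line coefficients. Agreement between lines had no test. Each line had 1 culture per condition, so the p-values rest on the spread between the 3 pairs.

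The named genes were fixed by rule as the reductase subunits RRM1, RRM2 and RRM2B, the 12 largest rises and 12 largest falls among genes past the threshold that moved the same way in all 3 lines (filled by smallest raw p where fewer passed), up to 4 members with the smallest raw p and any passing member of each list, and the 4 genes highest in each line among those past the F test. Y chromosome genes, XIST and TSIX were left out when the genes highest in each line were picked.

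The fit was tested on simulated signals of the 6 arrays with 200 changed genes among 14627 features. For the comparison of 3-AP with vehicle it called 71.6% of genes changed by 1 log2 unit, 88.1% of those changed by 2 and 92.4% of those changed by 3, with 9 calls of unchanged genes. Of 26 lists it called 1, the one that had been shifted. The changed genes were drawn outside the lists and not among the dimmest genes, so the shares called do not hold for dim genes. Each simulated change was of equal size in the 3 lines, so the shares do not hold for responses that vary between lines. In the real comparison the smallest change among features that passed was 1.17 log2 units after background subtraction. The simulated changes were set on the deposited scale, before that step, and those of 1 log2 unit had a median fitted size of 1.22. The real and simulated sizes are thus on unlike scales: SFXN5, which passed, had 0.48 in the deposited table. The simulated genes were independent of each other, so the simulation says nothing of correlated genes. The alternatives tried were the background step, the normalization, the offset, the detection filter, the probe rule, the variance model, the thresholds, the set test, the pairing and leaving out each line. Alternatives chosen after seeing the data were normexp without detection p-values, the non-normalized signals of BCBL1 and BC1, a detection filter on the 4 arrays with p-values, the averaging of the pairs labelled BCP1 and BCBL1, and the test of each line's response against the other 2.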

Results

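Primary effusion lymphoma is a B cell lymphoma that grows in body cavities and carries Kaposi sarcoma-associated herpesvirus. The cell lines BCP1, BCBL1 and BC1 derive from it. The agent 3-AP (triapine) inhibits ribonucleotide reductase, the enzyme that makes deoxyribonucleotides for DNA synthesis. Transcripts were measured on 6 arrays, 3 with vehicle and 3 with 3-AP at 2.5 µM for 48 h, 1 pair per line. On the 4 arrays with their own detection p-values, between 37.0% and 39.2% of 47323 probes were detected at p under 0.05. The arrays labelled BCP1 and BCBL1 resembled each other more than either resembled BC1, as described with the line differences.

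The first comparison asked which genes differed between 3-AP and vehicle within lines. Fold changes are given after background subtraction. In the processed table as deposited, without it, all 38 named genes that passed had smaller fold changes, 21 of them by more than 1.5 times, and values in brackets are the folds there. The largest rises were of small non-coding RNAs, of which only some rose. Of 136 small non-coding and ribosomal RNA features 12 passed, and these RNAs were not tested as a group. The 7SK RNA RN7SK, a regulator of transcription elongation, rose by 4.63 ± 0.14 on the log2 scale (SE, n = 3 pairs, limma adjusted p = 0.00188), which is 24.8-fold (18.6-fold). The 5S ribosomal RNA RNA5S9 rose 23.9-fold (16.9-fold) and the U3 small nucleolar RNA SNORD3D 23.5-fold (12.3-fold). The other U3 genes SNORD3C and SNORD3A rose 14.1-fold (8.35-fold) and 8.46-fold (6.70-fold). Among spliceosomal RNAs, RNVU1-7, RNU1-3, RNVU1-18 and RNU1-1 rose by 13.9-fold to 17.6-fold (7.95-fold to 11.6-fold), and RNU6-1 rose 5.43-fold (4.74-fold). RNU2-1 was not above background on any vehicle array and rose (adjusted p = 0.0448), at least 12.4-fold after background subtraction and 4.33-fold in the deposited table. The Y RNA RNY5 rose 9.11-fold (3.17-fold). These near-identical gene copies (U1, U3) can share signal between probes, so single copies are uncertain. The 28S and 18S ribosomal RNA features RNA28SN5 (2.93 ± 0.55 SE) and RNA18SN5 (1.70 ± 0.36) did not pass. Medians were -0.21 over box H/ACA small nucleolar RNAs and -0.33 over box C/D ones other than U3. RIMBP3 completed the 12 largest rises at 19.5-fold (6.23-fold).

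Protein-coding genes that rose included the chemokine genes CCL3, 8.13-fold (3.47-fold in the deposited table), and CCL3L1, 6.67-fold (2.72-fold), which are close copies of each other. The AP-1 subunit JUN rose 4.32-fold (1.90-fold), RGS1, a regulator of G protein signalling, 4.30-fold (2.24-fold), and LY96, which encodes the MD-2 co-receptor, 3.36-fold (2.87-fold). The small GTPase gene RHOB rose 2.84-fold (2.57-fold), with log2 fold changes of 1.55, 1.41 and 1.55 in BCP1, BCBL1 and BC1. PBXIP1, MELTF, MFGE8, HINT3, SP140, SFXN5, LAX1 and CFAP119 also passed, at 2.25-fold to 2.86-fold (1.39-fold to 2.63-fold). Another kept probe of HINT3 had a log2 fold change of -0.27, and the mean of all kept probes gave HINT3 0.59.

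Among the 11 named genes that fell, 2, PLK1 and AURKA, are in the fixed list of G2/M and mitosis genes. The largest fall was of another gene. PSRC1, a spindle protein gene, was 4.47-fold lower with 3-AP (log2 fold change -2.16 ± 0.18 SE, limma adjusted p = 0.0414), and 1.85-fold lower in the deposited table. The mitotic kinase genes PLK1 and AURKA were 3.35-fold (2.57-fold) and 2.46-fold (2.22-fold) lower. The transcription factor gene MYC was 2.58-fold lower (2.48-fold), with log2 fold changes of -1.27, -1.24 and -1.60 in BCP1, BCBL1 and BC1. The helicase gene PIF1 was 2.66-fold lower (1.76-fold) and the linker histone gene H1-10 2.65-fold lower (2.09-fold). The histone gene H2AC13 was not above background on any 3-AP array and was at least 2.33-fold lower after background subtraction and 1.48-fold lower in the deposited table. PRKCQ-AS1, IGDCC4, SLC39A10 and NAA15 were 2.36-fold to 2.74-fold lower (1.48-fold to 1.89-fold). CDC20, which activates the anaphase-promoting complex, was the next by raw p at 3.52-fold lower (3.22-fold) and did not pass (adjusted p = 0.0516).

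**Figure D1:**
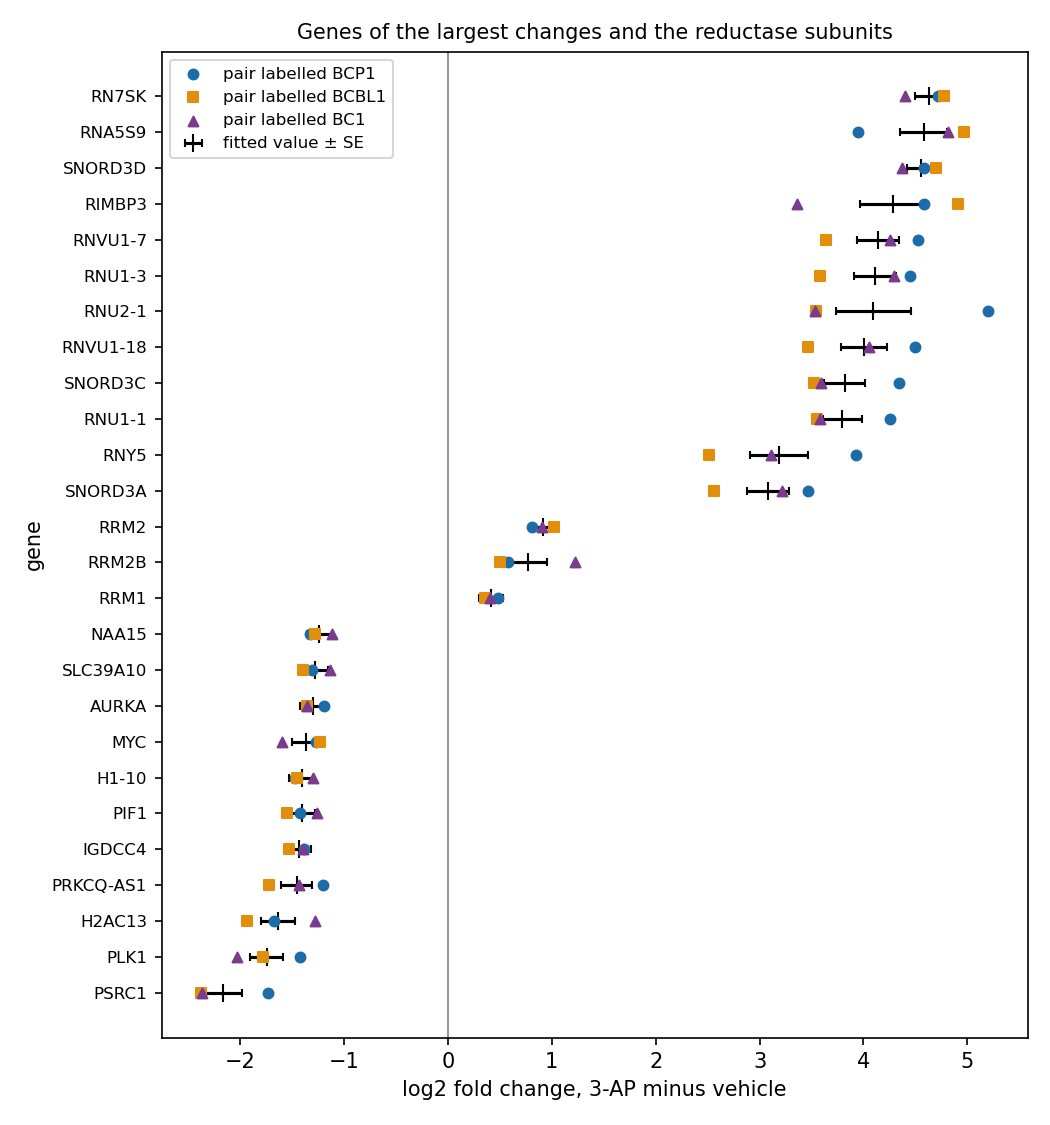
The x axis gives the log2 fold change, 3-AP minus vehicle, of the 12 largest rises, the 11 largest falls and the 3 reductase subunits, 1 gene per row. Coloured points are the pairs labelled BCP1, BCBL1 and BC1 and the black mark is the fitted value with its SE; every gene drawn moved the same way in all 3 pairs.

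In all, 50 of 14627 features passed, 36 higher and 14 lower. All 50 moved the same way in the 3 lines, which passing this paired test nearly requires. Of all features 49.4% moved the same way. Of the 50 that passed, 38 had a gene symbol, 27 higher and 11 lower, and 12 were unnamed probes. The raw p was under 0.05 for 3510 features against 731 by chance alone. The count depended on the processing. It was 1150, with 599 higher and 551 lower, in the processed table as deposited, 1399 with a variance trend and 3 without BC1. Without the pairing by line ("no replicate block") it was 10.

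The 3 subunits of the drug's target had positive log2 fold changes in all 3 lines and none passed. The values were 0.91 ± 0.12 (SE) for RRM2, adjusted p = 0.0640, 0.77 ± 0.18 for RRM2B, adjusted p = 0.112, and 0.41 ± 0.12 for RRM1, adjusted p = 0.140, by limma with n = 3 pairs. In their list of ribonucleotide reductase and dNTP supply genes, 0 of 16 members passed over all genes, and 3 higher (RRM2, TK1 and RRM2B) passed when adjusted over the list alone.

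The second comparison asked whether fixed gene lists shifted with 3-AP against the other genes. With the preset correlation, 6 of 26 lists shifted, 2 down and 4 up. With an estimated correlation none did (adjusted p = 0.677 for each of the 6), and fry, which does not compare a list with other genes, called none. The list calls therefore hold only in the version with the preset correlation. The estimated version also weakened lists whose estimated correlation was below the preset. For plasma cell markers, at an estimated correlation of -0.06, the camera raw p was 0.0538 preset and 0.177 estimated. Its losses thus do not come from the correlation alone. When camera estimates the correlation, it refers each list to the 2 residual degrees of freedom. Even G2/M and mitosis then had a camera raw p of 0.0886, against 6.37e-17 preset. The estimated version could therefore hardly pass any list, and its adjusted p-values speak neither for nor against one.

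Genes of G2/M and mitosis had a median log2 fold change of -0.56 over 36 members (camera adjusted p = 1.66e-15, and 0.677 with an estimated correlation), and 35 members were negative. PLK1 and AURKA passed over all genes, and 28 members, all lower, passed when adjusted over the list alone. CDC20 (-1.82), HMMR (-1.26) and the cyclin gene CCNB1 (-1.06) were among the 28. Genes of ribosome biogenesis and MYC targets had a median of -0.53 over 29 members, all negative (adjusted p = 4.70e-08, and 0.677 with an estimated correlation). MYC passed over all genes, and MYC and the nucleolin gene NCL (-0.74) when adjusted over the list alone. The list's median was -1.03 in BC1, -0.27 in BCBL1 and -0.22 in BCP1, and -0.28 without BC1 (replicate 3).

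Interferon response genes had a median of 0.71 over 19 members (adjusted p = 2.62e-06, and 0.677 with an estimated correlation). The median was 1.01 in BC1, 0.39 in BCBL1 and 0.38 in BCP1. It was 0.39 without BC1 (replicate 3), 0.30 in the processed table as deposited and 0.31 with the strict detection filter (p under 0.01 on all 6 arrays). None passed over all genes, and 8, all higher, passed when adjusted over the list alone. IFIT2, an antiviral effector gene, was not above background on any vehicle array, and its 3-AP level was at least 2.35-fold higher after background subtraction and 1.52-fold in the deposited table. PARP9 had a log2 fold change of 1.40 ± 0.24 (SE), and 0.70 in the deposited table. The list that holds CDKN1A and MDM2, damage response genes, had a median of 0.37 over 25 members (adjusted p = 6.45e-05, and 0.677 with an estimated correlation). CDKN1A, the cyclin-dependent kinase inhibitor p21, had a log2 fold change of 2.41 ± 0.26 and did not pass over all genes (adjusted p = 0.0516). It passed in 11 of the 19 alternatives to the processing that are described below. CDKN1A and EDA2R (1.03, and 0.42 in the deposited table) passed when adjusted over the list alone. MDM2 had 1.06 ± 0.31. The list's median was 0.92 in BC1, 0.26 in BCBL1 and 0.19 in BCP1. It was 0.28 without BC1 (replicate 3) and 0.56 without BCBL1 (replicate 2).

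NF-kB targets had a median of 0.26 over 23 members (adjusted p = 0.00485, and 0.677 with an estimated correlation). CCL3 passed over all genes, and CCL3, EBI3, CCL5 and RELB when adjusted over the list alone. The call was lost without the pairing block (adjusted p = 0.134) and with cell line as a random block (adjusted p = 0.0821), and the median was 0.40 without BCP1 (replicate 1). Mature B cell markers had a median of 0.49 over 11 members (adjusted p = 0.0230, and 0.677 with an estimated correlation). None passed over all genes. The 5 that passed when adjusted over the list alone were CD79B, a B cell receptor subunit gene, and the class II antigen presentation genes CD74, HLA-DMA, HLA-DMB and HLA-DPA1. The CD79B probe was not above background on any vehicle array. Its log2 fold change was 1.42, but 0.48 in the deposited table and 0.40 for the other kept probe. Of the 11 members 8 were positive and 3 negative, among the latter CD79A (-0.50). The call for mature B cell markers was lost without BCBL1 (adjusted p = 0.0733) and without the pairing block (adjusted p = 0.0522). The list's median was 0.23 with no filter on dim probes and 0.32 in the processed table as deposited.

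The other 20 lists did not shift. Immediate early and AP-1 genes had a median of 0.30 (adjusted p = 0.0956). JUN passed over all genes, and 8 higher and 3 lower members when adjusted over the list alone. Unfolded protein response and ER chaperone genes had a median of 0.10, iron handling 0.23, apoptosis regulators 0.11, plasma cell markers 0.13, and G1/S cyclins and E2F genes 0.16. In the last list CCNE1 had 1.13 ± 0.16 (SE). The medians were 0.03 for ATF4 and amino acid response genes, where DDIT3 had 1.34 ± 0.15, 0.05 for the cytokine and JAK/STAT list, and 0.04 for hypoxia and HIF targets. Replication-dependent histones had 0.28, replication stress and DNA repair 0.09, T and NK cell markers 0.10 and myeloid and dendritic cell markers 0.06. Oxidative phosphorylation had 0.03, cytosolic ribosomal proteins -0.01, DNA replication machinery -0.04, cholesterol synthesis -0.05, heat shock, metallothionein and oxidative stress -0.07 and glycolysis -0.13.

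**Figure D2:**
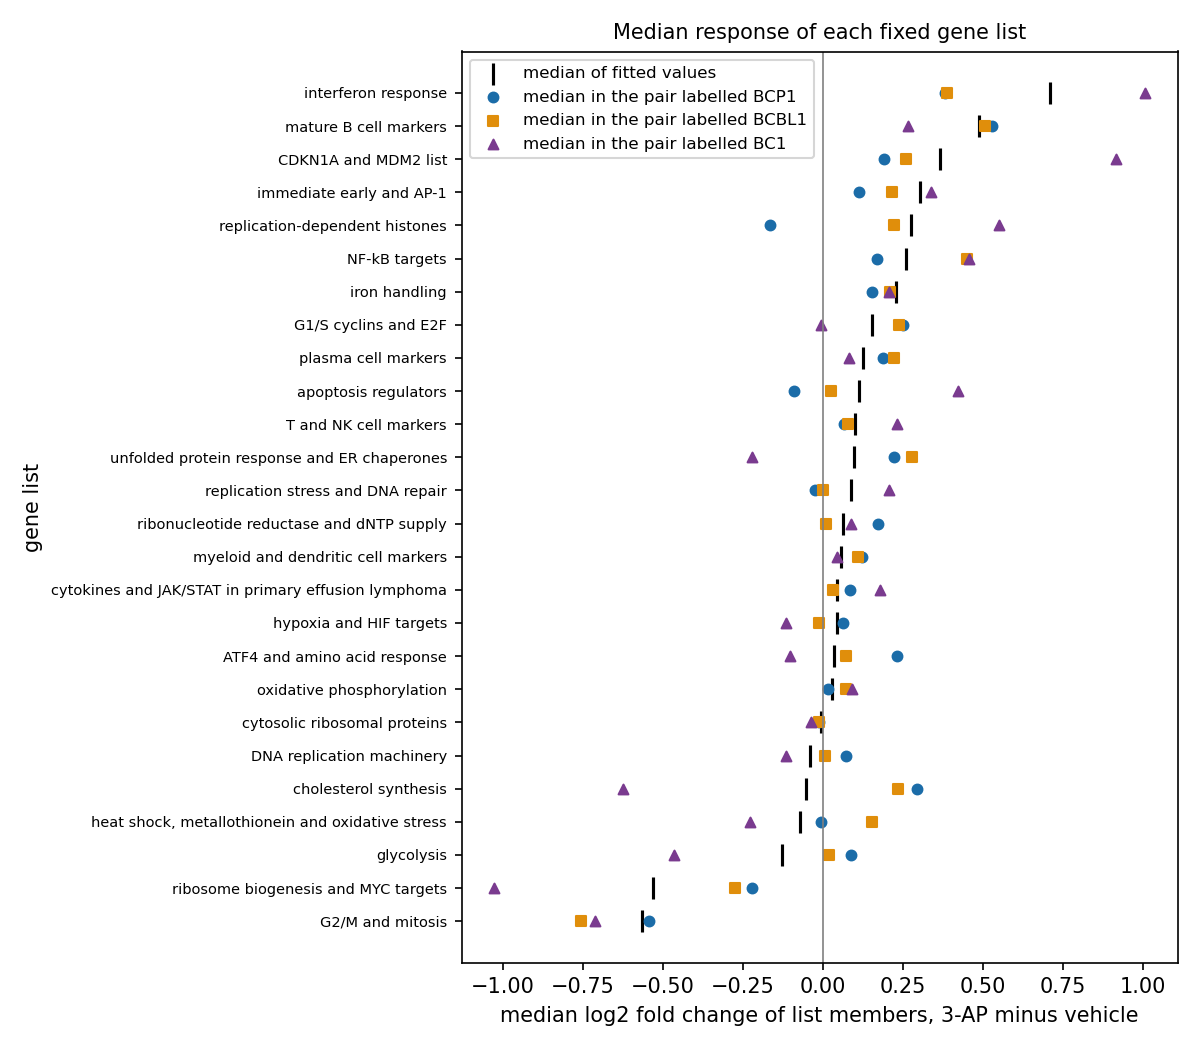
The x axis gives the median log2 fold change, 3-AP minus vehicle, of each of the 26 fixed lists, 1 list per row, in each pair (coloured points) and over the fitted values (black mark). G2/M and mitosis lies lowest at -0.56 and interferon response highest at 0.71.

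The third comparison asked how far the lines agreed. Across 14627 features, which are not independent replicates, the log2 fold changes of BCP1 and BCBL1 had a Pearson correlation of 0.60 and a Spearman correlation of 0.54. The values were 0.42 and 0.36 for BCP1 with BC1, and 0.45 and 0.39 for BCBL1 with BC1. BC1 had the most features changed at least 2-fold, 559 up and 550 down, against 309 and 221 in BCBL1 and 281 and 175 in BCP1. In all 3 lines 73 were at least 2-fold up and 32 at least 2-fold down. In the deposited table these counts were 194 and 141 in BC1, 53 and 13 in BCBL1, 58 and 9 in BCP1, and 28 and 5 in all 3 lines. Each line's change came from 1 array against 1 and has no replicate check.

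The fourth comparison asked which genes differed between lines. BC1 stood apart. ITM2A, a membrane protein gene, was 477-fold higher in BC1 than in the mean of the other lines (limma F test adjusted p = 0.000263). SH3GL2 was 48.4-fold higher, with log2 levels of 12.18 in BC1, 7.85 in BCP1 and 5.31 in BCBL1. The carbonic anhydrase gene CA2 was 46.8-fold and the adenylate kinase gene AK4 30.3-fold higher. In the deposited table these folds were 106 for ITM2A, 19.5 for SH3GL2, 18.1 for CA2 and 8.13 for AK4. The 4 genes highest in BCP1 were also high in BCBL1. Of these the thrombospondin gene THBS1, GTSF1 and the cancer-testis gene CT45A1 were not above background in BC1 and were at least 212-fold, 216-fold and 175-fold higher in BCP1 after background subtraction, and 63.6-fold, 60.1-fold and 52.5-fold in the deposited table. CT45A3 had a mean log2 level of 14.05 in BCP1, 14.02 in BCBL1 and 5.12 in BC1, and was 117-fold higher in BCP1 than in BC1 in the deposited table. In BCBL1 the surrogate light chain gene IGLL1 was at least 182-fold higher than in BC1 after background subtraction and 52.0-fold in the deposited table. MGST1 had a log2 level of 13.07 in BCBL1, 12.99 in BCP1 and 4.95 in BC1. Its probe was not above background in BC1, so the BC1 level is only a floor, and the deposited table gave 60.0-fold for BCBL1 over BC1.

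In all, 2962 features passed the F test. None differed between the arrays labelled BCP1 and BCBL1 in limma's contrast (988 at a raw p under 0.05), against 3279 between BCP1 and BC1 and 3613 between BCBL1 and BC1. At least 4-fold differences between vehicle arrays numbered 11 for BCP1 and BCBL1, 620 for BCP1 and BC1 and 666 for BCBL1 and BC1. Among probes of the deposited table they numbered 0, 235 and 245. Without BC1, no feature passed.

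**Figure D3:**
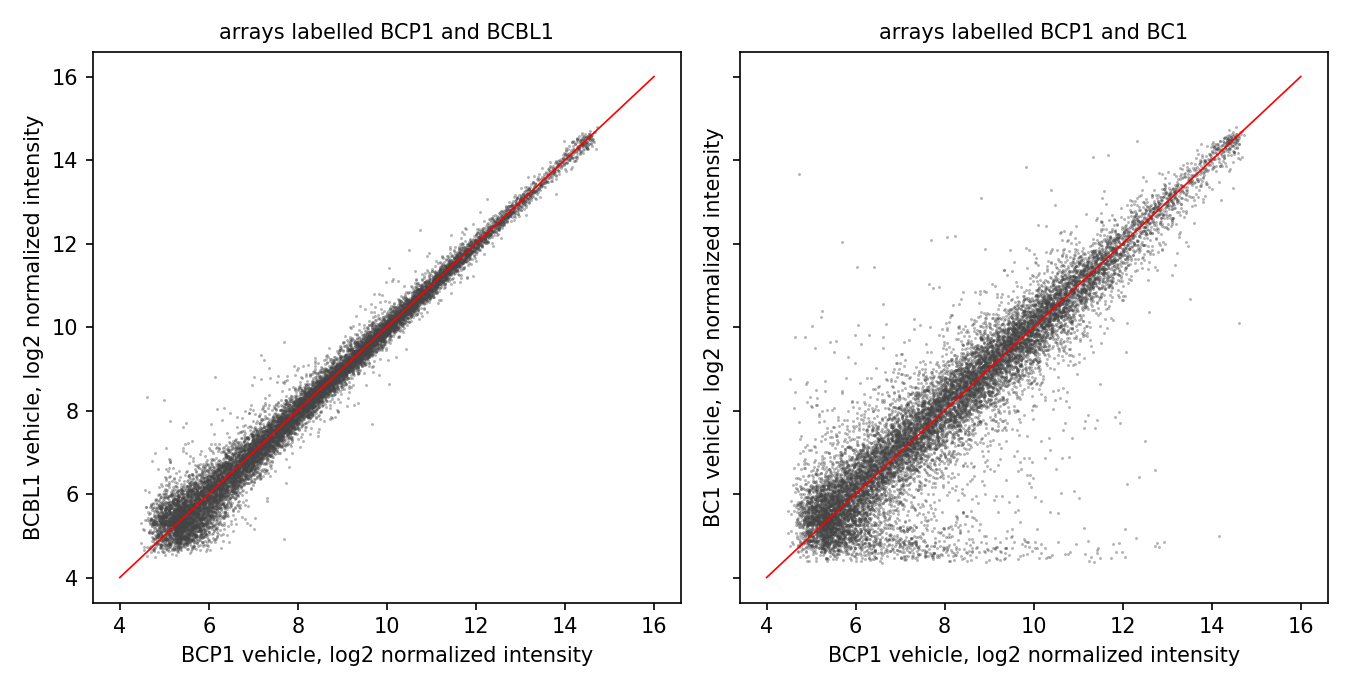
Each point is 1 of 14627 features, plotted by its log2 normalized intensity on the BCP1 vehicle array (x axis) and on the BCBL1 (left) or BC1 (right) vehicle array (y axis). The red line marks equal levels; 11 features lie at least 4-fold off it on the left and 620 on the right.

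Most plasma cell markers were detected in all lines. Of 18 on the array, 13 were detected on all 6 arrays, among them IRF4, PRDM1 and SDC1. JCHAIN, CD27 and POU2AF1 were detected on none, DERL3 on 1 and MZB1 on 4. Between lines 4 differed. TNFRSF17 was lower in BC1 (log2 level 10.02) than in BCP1 (11.05) and BCBL1 (10.98), as was XBP1 (11.12 against 11.98 and 12.04). CD38 was higher in BC1 (9.53) than in BCP1 (7.83) and BCBL1 (7.88), as was ELL2 (10.62 against 9.38 and 9.33). Of 23 mature B cell markers 7 were detected on all arrays: CD74, HLA-DRA, HLA-DPA1, HLA-DMA, HLA-DMB, CIITA and BACH2. On no array were 6 detected, PAX5, BLK, EBF1, CD72, CD52 and TCL1A, and MS4A1 and CD22 were detected on 1. Of 18 T and NK cell markers only IL2RB was detected on all 6 arrays. Of 20 myeloid and dendritic cell markers 3 were, CD68, LYZ and AIF1.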

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

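The test of each line's response against the mean of the other 2, and the tests of that pattern except the one on the non-normalized signals, were chosen after the result was seen. A list is given here where that interaction term had an adjusted p under 0.05 by limma camera with a preset correlation, over 78 tests. The 3 terms share the same 3 responses and are not independent. Each fit had 1 residual degree of freedom, the difference between the responses of the other 2 lines. For BC1 that spread is BCP1 against BCBL1, whose arrays resembled each other, so a small spread there makes BC1 stand out. When camera estimates the correlation, it refers each list to the residual degrees of freedom, here 1. Even a strong difference can then hardly pass, so that version speaks neither for nor against a list. With an estimated correlation no list differed (adjusted p = 0.987 for each list given), and no single gene passed for any line (raw p under 0.05 for 2606 features in BC1, 441 in BCBL1 and 395 in BCP1, with 731 expected).

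The values here are medians, over the genes of a list, of each gene's log2 response in the line minus its mean response in the other 2, and they are not differences between the medians of the list. In BC1 this median difference was 0.83 for the CDKN1A and MDM2 list, 0.91 for replication-dependent histones and 0.56 for interferon response genes. It was -0.81 for ribosome biogenesis and MYC targets, -0.88 for cholesterol synthesis, -0.54 for glycolysis, -0.28 for heat shock, metallothionein and oxidative stress, and -0.32 for unfolded protein response and ER chaperone genes. In BCBL1 the median differences were -0.42 for the CDKN1A and MDM2 list, 0.27 for ribosome biogenesis and MYC targets, 0.18 for heat shock, metallothionein and oxidative stress, 0.19 for unfolded protein response and ER chaperone genes and 0.36 for cholesterol synthesis. In BCP1 they were 0.35 for ribosome biogenesis and MYC targets, -0.64 for replication-dependent histones, 0.38 for glycolysis, 0.47 for cholesterol synthesis, -0.37 for the CDKN1A and MDM2 list, 0.23 for G2/M and mitosis, -0.26 for NF-kB targets and -0.17 for interferon response genes.

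Whether the authors' normalization is the source of the BC1 pattern was not decided. Starting from the non-normalized signals, 8 of the 8 lists kept the sign of BC1 minus BCBL1. Those signals were also background corrected and quantile normalized here. On each BCBL1 and BC1 array they had the same ranks as the processed values (Spearman correlation 1), so the signs could hardly change. The same response at another strength stays open. Of the 8 lists, 4 had median responses of opposite sign in BC1 and in the other lines, among them cholesterol synthesis (-0.62 against 0.28), but 1 pair gives no spread for BC1 and glycolysis and heat shock lay near 0 in the other lines. For the same reason 1 unusual pair of arrays could be the source and cannot be told apart from a difference between the lines, which was not tested separately.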

How the results depend on the processing

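The count of 50 genes changed by 3-AP depended on the processing, and the cause was not tested except where fewer samples or another threshold was the alternative itself. It was 1197 without background correction, 1150 in the processed table as deposited, 650 with offset 50, 654 with a detection p under 0.01 on all arrays, 1399 with a variance trend and 447 with cell line as a random block. It was 21 with median scaling and 10 without a filter. Without the pairing ("no replicate block") it was 10. Leaving out 1 line gave 3 to 36: 3 without BC1, 20 without BCP1 and 36 without BCBL1. An adjusted p under 0.10 gave 776 and a raw p under 0.01 gave 1196. Of the alternatives chosen after seeing the data, normexp without detection p-values gave 244, the non-normalized signals of BCBL1 and BC1 gave 23, the filter on 4 arrays 26 and the averaging of the pairs labelled BCP1 and BCBL1 19. All of the 50 genes that were tested kept their direction in each alternative, and RN7SK and SNORD3D passed in all 19. Counted over alternatives, named genes that passed stayed past the threshold 482 times and lost it 225 times. Named genes that had not passed gained it 266 times, stayed short of it 1569 times and changed sign 4 times. MYC, PLK1 and AURKA each passed in 10 of 19. CDKN1A and CDC20, which did not pass in the main version, passed in 11, and RRM2 in 7. The 6 lists became 0 with fry and 0 with an estimated correlation, a version that could hardly pass any list on 2 residual degrees of freedom. Over all alternatives called lists stayed past the threshold 104 times and lost it 16 times. The mean Pearson correlation between lines, 0.49, was 0.61 without background correction, 0.61 in the deposited table, 0.62 with the strict filter and 0.33 with no filter. The count of genes differing between cell lines, 2962, became 0 without replicate 3 (BC1), 2709 without replicate 1 (BCP1) and 2852 without replicate 2 (BCBL1). Named genes that did not pass changed sign in few cases: the log2 fold change of FCGR3A, -0.210, was 0.0770 without replicate 1, -0.370 without replicate 2 and 0.0734 in the non-normalized signals of BCBL1 and BC1 only. That of IL7R was 0.146 without replicate 2 and -0.260 without replicate 1, and that of ZAP70 was -0.0577 without replicate 3 and 0.251 without replicate 1. Arrays could be split into 3 and 3 in 10 ways, too few for a share under 0.05. For genes the real split gave 50 and the highest other 0, so 1 of 10 was as large. For lists the real split gave 6 and the highest other 9, and 8 of 10 were as large. The 3 other splits that part every pair, each exchanging the arrays of 1 line, gave 0 genes and 6, 8 and 9 lists. Every other split still held responses to 3-AP, so its counts do not measure chance alone.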

Other observations

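Except for the comparison of small RNA classes, the tests given here were chosen after the results were seen. The 12 small non-coding RNA features that rose were the 7SK feature, the 5S feature, all 3 U3 features, 6 of 11 spliceosomal RNAs and 1 of 4 Y RNAs. Among spliceosomal RNAs that did not pass, RNU6ATAC had a log2 fold change of 1.59, RNU4-2 1.37, RNU4-1 1.22, RNU4ATAC 1.09 and RNU11 0.42. The Y RNAs that did not pass were RNY4 (0.90), RNY3 (-0.18) and RNY1 (-0.49). RMRP had a log2 fold change of 2.11 ± 0.27 (SE) and RPPH1 1.25 ± 0.16, and neither passed. The 7SL RNA RN7SL1 had 0.40. The median was -0.21 over 37 box H/ACA small nucleolar RNAs, -0.33 over 41 box C/D ones other than U3 and -0.20 over 25 microRNA precursors, and none of these passed.

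The deposited normalization is argued against as the source of the rise of 12 small non-coding RNA features, whose median 3-AP to vehicle ratio in the non-normalized signals was 7.30 in BCBL1 and 9.48 in BC1 (all features, 1.03 and 0.987). More non-polyadenylated RNA labelled in the treated samples could also raise them, and a median under 0.2 over the classes with no risen member was set, before any value was seen, as speaking against this. The first value was -0.16. After it was seen, 5 microRNA host genes were taken out (116 features, median -0.19), and the test was made undecided where classes go both ways, as they do here: large ribosomal RNA had a median of 2.31, and probes for small nucleolar RNAs and microRNAs can also read host transcripts. The labelling explanation therefore stays open beside an effect of 3-AP, which was not tested separately.

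The arrays labelled BCP1 and BCBL1 resembled each other. That 1 array was deposited under both names is argued against, since the ranks of their vehicle arrays as deposited had a Spearman correlation of 0.878 over all probes, close to the 0.875 between the vehicle and 3-AP arrays of BCP1. Whether 1 line stands under 2 labels was not decided: 0 genes differed between them, against 3279 and 3613 from BC1, but this is the resemblance itself and no separate test of its source, and 988 features had a raw p under 0.05 against 731 by chance. A true likeness of both lines stays open too. If they are 1 line, the count of 50 genes rests on 2 lines, and averaging their pairs gave 19.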
